A study of Mus musculus with 6 samples.

How the data were processed

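Chromatin fragments carrying H3K4me3, H3K27ac or H3K27me3 were measured by position in 6 mouse tissue sections, with 1 section per combination of tissue, condition and mark. Per the labels' protocols, sections lay on DNA arrays printed with barcode pairs, a primary and a secondary antibody bound the mark, and protein A-Tn5 loaded from the array cut the chromatin once magnesium was added. The embryo sections were 16 µm and the brain section 20 µm thick and were cryosectioned. The paw sections were fixed, decalcified, embedded in paraffin and sectioned at 4 µm around the talus, a bone of the ankle.

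Per the submitters' processing notes, Bowtie2, featureCounts and MACS2 were used, with no versions given, and the genome builds hg19 and mm9 were named. The roles of the tools and builds are not given in the sources used here. The deposited values are signal values per gene and array spot, which the authors quantile-normalised. In all 6 sections the 500 highest values of every spot formed the same list, multiplied by 1 factor per spot, apart from rounding of the stored numbers. The number of values above 0 was equal over the spots of the brain and of each paw, and differed in the embryo (2023 to 4046 for H3K27ac, 3279 to 4688 for H3K27me3, 1424 to 2695 for H3K4me3). In the spot with the most values above 0, 100% of the common values were whole multiples of a single step, to within 0.001 of that step. Within a spot, genes of equal count had been ranked in the order in which the control paw lists its genes. Genes without reads therefore received values above 0 if they stood late in that order. The brain and the arthritis paw list their genes in the same order. The embryo sections list them alphabetically, and their genes were put in the control paw's order before any further step. Between 46.3% and 68.9% of the deposited values above 0 belonged to such genes. Across genes, Spearman's rho between the mean deposited value and the place in the order was 0.330 to 0.584.

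Because of that dependence, reads were recovered from the tied ranks. Within a spot, the place in the order only rises among genes of equal count and falls back at the next count, so each fall marks 1 further read. A count held by fewer than 5 genes ended the zone in which numbers are exact, and a gene with more than 10% of its reads beyond that zone has a sum that is a lower bound, which was so for 60 to 197 genes per section. The sum over spots of each sorted rank was compared with the common list of values in units of its step: 76.5% (brain) to 99.5% (arthritis paw) of ranks were equal as whole numbers, and the recovered total was 92.9% to 95.4% of the list's total. At the highest rank far more was missing. The recovered sum there was 10308 against 72284 in the brain, 16739 against 114007 in the arthritis paw and 18948 against 109588 in the control paw. For embryo H3K27ac, H3K27me3 and H3K4me3 it was 3264 against 13677, 4194 against 17300 and 3384 against 8851. Sums that are lower bounds may therefore be several-fold too low. Recovered reads correlated with the place in the order at -0.108 to -0.0594. The choice of recovered reads over deposited values for the reported results was made after the values were seen. The formulas, gene lists, named-gene rule and first set of alternatives were fixed before the data were examined, and list percentiles, correlations, shares by Moran's I and regions were also computed from the deposited values.

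The recovery was tested on simulated data, in which the 2 paw sections were drawn from known read numbers and passed through the same normalisation. The simulation took ties ranked in gene order and Poisson counts as given, so it tests the decoding and cannot test that ranking. It recovered 99.4% (arthritis) and 98.8% (control) of the simulated reads, against 95.4% and 92.9% of the list's total in the real sections. The brain and embryo sections were not simulated. Of the simulated entries with reads, 99.7% (arthritis, 11130 genes) and 99.5% (control, 19378 genes) were recovered with the same number. Planted changes by factors of 0.25, 0.5, 2 and 4 in 50 genes each gave median log2 shifts of -1.37, -0.89, 0.88 and 1.76, and 100% of the genes moved in the planted direction. The 10930 unchanged genes shifted by a median of -0.03 with a standard deviation of 0.11. Apart from the simulated data, 200 random lists of 15 genes were placed by the recovered sums of the real paws. Of these, 5% fell outside the central 95%. The procedure gives about that share by construction, so this checks the calculation alone.

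For each section, a gene's reads were averaged over spots and divided by the mean over the genes held by both compared sections. The log2 ratio of 2 sections was taken after a pseudocount of 0.1 on that relative scale was added. Between sections, 5 comparisons were made, and the 15 pairs of sections were correlated across genes. A total of 32 gene lists (17 for the paw, 8 for the embryo, 7 for the brain) were written down beforehand from textbook markers and pathways. The median log2 ratio of each list was placed among 10000 random lists matched gene by gene in 20 bins of mean signal, and a list beyond 2.5% in either tail was called outside. The number of lists outside as the measure that answers a comparison was settled after a first look at the values. Percentiles describe a list among the genes of these sections and are not p-values, and no gene was tested singly because each group holds 1 section.

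Named genes followed a fixed rule. Among genes held by both sections, with a relative mean at or above the median and the same sign of the log2 ratio in odd and even array columns, the 15 highest and 15 lowest ratios were taken (10 and 10 for embryo comparisons), together with 3 members per list farthest in the direction of the list's median. For each section the 10 genes with the highest Moran's I and for each region the 5 leading genes were taken. Genes singled out by array row, by array column or by presence in all sections were chosen after their values were seen. Symbols were matched without regard to case to the reference annotation of assembly GRCm38.p6, in which 19262 of 19378 were found. The annotation served for names and neighbouring genes alone, and no coordinates are given because the submitters' notes name other builds.

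Within sections, reads of each spot were scaled to the section's median depth, and Moran's I was computed over 8 neighbours for genes at or above the median signal, against 1 shuffling of the spots. A further reference drew every spot from a single profile at its real depth by Poisson sampling. Regions came from k-means with 6 clusters on 20 principal components of 2000 variable genes after averaging over neighbours, and are numbered without cell types. A gene was called raised in an array row or column when it held at least 100 reads, with at least 20 in that line and at least 5 times the section's share. Shares carry 95% Wilson intervals, ratios of reads exact Clopper-Pearson intervals and medians of lists intervals from Poisson resampling. Those of reads, ratios and list medians cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Reads missing from lower-bound sums are not covered either, so the intervals and the order of such genes can be off. Those of shares of genes by Moran's I take genes as independent, although all genes share the same spots, depths and 1 shuffling. They hold no spread of the shuffling or of the single profile.

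Alternatives fixed beforehand were pseudocounts of 0.01 and 1, genes at or above the median signal, ranks in place of ratios, scaling by the median, spots at or above the 25th percentile of genes with reads, odd or even columns, the share of spots with reads, a trimmed mean (10% from each end), 4 neighbours, presence above the gene's median, 4 or 8 regions and no smoothing. Those added later are named in the closing section, and their effects are given where a call, a count of lists or a share changed. Genes held by 1 of 2 compared sections were left out of the ratios. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, scikit-learn 1.9.0 and Matplotlib 3.10.9. Single values of 2 genes withheld for evaluation are not reported here.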

Results

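Histone marks were profiled by position in 6 mouse tissue sections on DNA arrays, in which an antibody against the mark recruits protein A fused to Tn5, a transposase that cuts the marked chromatin and ties it to the barcodes of its spot. H3K4me3 is found at active promoters, H3K27ac at active promoters and enhancers, and H3K27me3 over genes held silent by Polycomb complexes. The embryo at E11.5 was profiled in 3 sections, 1 for each mark, and the adult brain in 1 section for H3K4me3. The paw was profiled for H3K27ac in 1 section from a mouse with collagen-induced arthritis, a model of inflammatory joint disease, on day 42, and in 1 section from a control. With 1 section per group there was no spread between animals to set a difference against, so all values below describe these sections.

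The sections held 15064699 recovered reads in 3450 spots. The arthritis paw held 5344438 reads in 943 spots, the control paw 5981684 in 554, the brain 2036521 in 1200, and the embryo sections 548923 (H3K27ac, 251 spots), 749650 (H3K27me3, 254 spots) and 403483 (H3K4me3, 248 spots). Median reads per spot were 5296 and 10114.5 in the arthritis and control paws, 1179 in the brain, and 1972, 2596.5 and 1481.5 in the embryo in the same order of marks. The median gene held 274, 142 and 120 reads in the arthritis paw, control paw and brain, and 12, 14 and 7 in the embryo, which limits what single genes can show there.

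The comparison of the paws asks which genes differ in H3K27ac in an inflamed joint. Epidermal genes held by both paws carried more H3K27ac reads in the arthritis paw, with a median log2 ratio of 0.54 (counting interval 0.40 to 0.69) against 0.11 over all genes compared. Klf4 and Trp63, transcription factors of the epidermis, lay at 1.58 and 0.85, and Krt1, a keratin of its upper layers, at 0.61. Genes of the interferon and JAK-STAT response were also higher, at 0.44 (0.28 to 0.53), among them the interleukin 6 receptor gene Il6ra at 1.47, the kinase gene Jak2 at 0.83 and the myeloid transcription factor gene Irf8 at 0.63. Neutrophil genes were lower, at -0.37 (-0.46 to -0.20), with Cebpe, a regulator of granulocyte maturation, at -2.41, the protease gene Elane at -0.77 and Camp, which encodes an antimicrobial peptide, at -0.73.

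Among 10000 matched random lists, the epidermal genes lay at percentile 98.8 (7 of 10 members above the median of all genes), the interferon genes at 97.6 (11 of 18) and the neutrophil genes at 0.57 (4 of 12). The comparison leaves out 8248 genes of the control paw and 0 of the arthritis paw. The control paw holds 20, 28 and 22 members of these lists in the same order, and the members missing in arthritis do not enter the calls. These 3 of the 17 paw lists fell outside the central 95%, where chance gives 0.85. Of the 15 lists drawn up for other tissues, 2 fell outside: brain neuron genes at 0.90 and astrocyte genes at 1.36. None of the 3 calls held under every setting: with genes of lower signal left out, the percentiles were 89.3, 52.5 and 6.25 in the same order. The interferon call also ended with the deposited values (84.3), a pseudocount of 1 (92.8), even columns (92.9), the share of spots (94.2), a trimmed mean (96.5) and without array columns 1, 5, 9, 13, 17 and 21 (97.1), the epidermal call with a pseudocount of 1 (96.5), ranks (95.6) and even columns (95.8), and the neutrophil call with odd columns (13.2).

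The lists of joint tissue and of immune cells other than neutrophils lay within the central range for the recovered reads. Outside it under an alternative were synovial fibroblast genes with the deposited values (1.34), B and plasma cell genes with ranks (2.49) and erythroid genes with genes of lower signal left out (1.12). Osteoclast genes had a median of 0.24 (percentile 62.9), with carbonic anhydrase 2, Car2, at 2.36 (994 reads against 131) and Nfatc1, the main transcription factor of osteoclast formation, at 1.27. Skeletal muscle genes lay at 0.28 (82.6), led by the calcium pump gene Atp2a1 at 1.70 and the myosin light chain gene Mylpf at 1.48, T and NK cell genes at 0.21 (75.6), led by Zap70 at 1.19, and cartilage genes at 0.20 (71.7), led by Cilp at 0.91. Macrophage genes lay at 0.07 (45.9), osteoblast genes at 0.03 (30.3), matrix-degrading enzymes at 0.00 (23.0), adipocyte genes at -0.01 (25.1), endothelial genes at -0.01 (22.8), inflammatory cytokines at -0.03 (18.4), genes of the NF-kB and AP-1 response at -0.04 (15.4), erythroid genes at -0.12 (8.56), synovial fibroblast genes at -0.18 (5.13) and B and plasma cell genes at -0.25 (4.56). Single members were far lower in arthritis than their list: the cathepsin gene Ctsl at -5.02 (187 reads against 6404), the cytokine gene Il17f at -3.44 (80 against 1134), the B cell gene Ms4a1 at -3.24 (267 against 2465), Jun at -2.93 and the endothelial receptor gene Kdr at -2.40. A planted 1.5-fold shift of all members placed each of the 17 lists above the central range, and in the other comparisons every list except 2 of 8 for H3K27me3 against H3K4me3, for which a 2-fold shift was enough. The planted shift was upward, equal in all members and without noise, after each list's own offset was removed. Changes in part of a list and downward changes were not tried.

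Of single genes, the highest in arthritis were Iqcf4 at 5.52 (4759 reads against 48), Ccr4, a chemokine receptor of helper and regulatory T cells, at 5.36 (4442 against 52), Cpsf7, a subunit of the mRNA cleavage machinery, at 5.33 (9904 against 168), and Dmap1 at 5.13 (4301 against 64). Casp12, H2-DMb2, which takes part in loading MHC class II molecules, and Psat1, an enzyme of serine synthesis, followed at 4.97, 4.92 and 4.57. Lowest were Taz at -7.44 (58 against 15484), Plscr4, a phospholipid scramblase, at -6.66 (117 against 13983), the splicing factor gene Isy1, which had the reads of its neighbour Cnbp in the control, at -6.56 (103 against 11974), the tachykinin receptor gene Tacr2 at -6.27 and the homeobox gene Hoxc8 at -5.67 (332 against 16285). Without the pseudocount, the ratio was 6.39 (5.98 to 6.83) for Iqcf4 and -8.31 (-8.70 to -7.94) for Taz. Lower bounds are the control sums of the 15 lowest genes, Ctsl and Jun, and the arthritis sums of 6 of the 15 highest, among them Iqcf4, Cpsf7 and Psat1. The order of these genes and the intervals of Iqcf4 and Taz do not allow for the missing reads. In the control paw Cebpe, Jun and Kdr held 5.77, 5.87 and 5.74 times their share in columns 1, 5, 9, 13, 17 and 21, and Elane had the reads of its neighbour Cfd to within 5%.

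**Figure D1:**
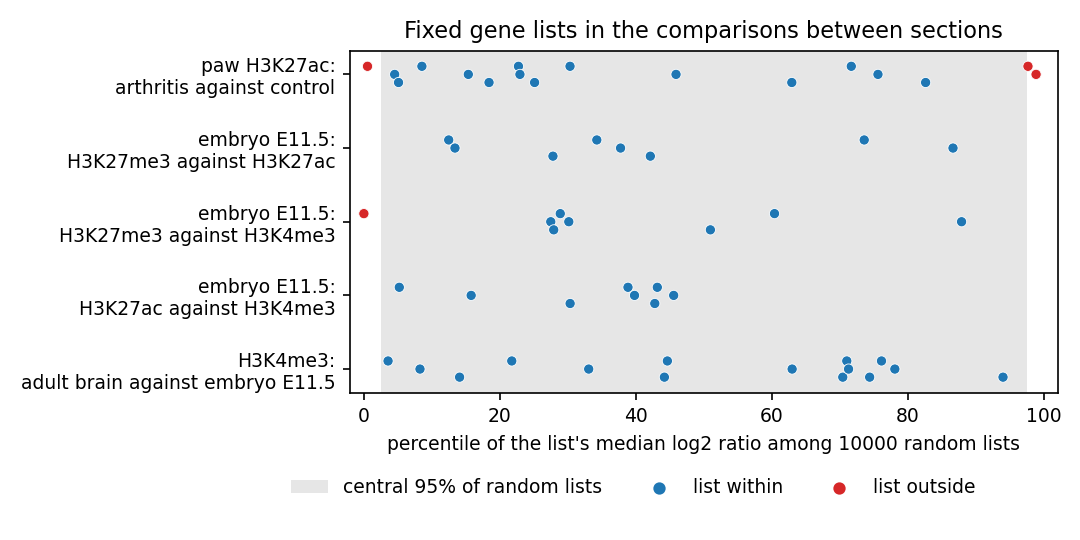
Position of each gene list drawn up for the compared tissues, as the percentile of its median log2 ratio among 10000 random lists (x axis, percentile), for the 5 comparisons between sections (y axis). Each point is 1 list, and red points lie outside the shaded central 95%: 3 of 17 in the paw, and 1 of 8 for H3K27me3 against H3K4me3.

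The embryo comparisons ask how a repressive mark and active marks divide the genes at E11.5. Between H3K27me3 and H3K27ac, developmental genes did not part as a group. The 38 Hox genes, which set position along the body axis and are textbook Polycomb targets, had a median log2 ratio of -0.16 (-0.29 to 0.05) against -0.12 over all genes, at percentile 37.8, and the 98 developmental transcription factors of Polycomb domains lay at -0.15 (34.3). With the deposited values these lists lay at 96.0 and 56.4, within the central range, so the place of the Hox genes depends on the processing. Single members went far toward H3K27ac, such as Hoxc13 at -5.48 (35 reads against 1270), Otx1 at -4.53 and Sox14 at -4.50. Housekeeping genes lay at -0.23 (13.4), with Cox4i1, a subunit of cytochrome c oxidase, at -3.60 (5 reads against 77).

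None of the 8 embryo lists fell outside the central range for this pair, where chance gives 0.4, and 1 of the 24 lists of other tissues did (T and NK cell genes, 98.7). Liver and blood genes lay at 0.06 (86.6), although the red cell anion exchanger gene Slc4a1 was at 3.64 and the globin gene Hba-a2 at 3.15 toward H3K27me3. Neural genes were at percentile 73.6, led by Nhlh2 at 5.64. Limb and facial genes lay at -0.14 (42.1), led by Lmx1b at -3.78, heart genes at -0.21 (27.8) and somite and muscle genes at -0.34 (12.5), led by Mesp2 at -3.04. With the deposited values the somite list alone was outside, at 0.64. The highest single ratios were those of Pold2, a subunit of DNA polymerase delta, at 8.22 (2813 reads against 4) and Acrbp at 7.71 (1117 against 1), and the lowest those of Rapsn, which clusters acetylcholine receptors, at -8.47 (2 against 1553), Lce1i at -7.58, Eppk1 at -7.33 and the connexin gene Gjb1 at -7.17. Without the pseudocount, Acrbp had a ratio of 9.68 (7.19 to 14.98) and Rapsn of -10.05 (-13.10 to -8.20). Among the 20 extreme genes, 6 had the reads of a neighbouring gene to within 5%, such as Hspa1l and Lsm2. The larger sums are lower bounds for 7 of the 10 highest genes and 5 of the 10 lowest, among them Pold2, Acrbp and the 4 lowest named, and for Hoxc13.

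Against H3K4me3, H3K27me3 was lower on housekeeping genes. Their median log2 ratio was -0.43 (-0.59 to -0.05) against 0.08 over all genes, at percentile 0.035, with 13 of 43 members above the median of all genes. The ribosomal protein gene Rplp0 lay at -2.70 (24 reads against 97), the glycolytic enzyme gene Gapdh at -2.55 (33 against 116) and the splicing factor gene Hnrnpa1, which shares reads with its neighbour Cbx5 in the H3K4me3 section, at -1.96 (49 against 110). Hox genes lay at 0.11 (51.0), led by Hoxc4 at 3.53 (257 against 10), and the transcription factors of Polycomb domains at 0.16 (60.4). With the deposited values these lists lay at 96.4 and 29.1, within the central range.

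This was 1 of 8 lists outside, where chance gives 0.4, and 0 of 24 lists of other tissues were. The other lists lay at 0.26 (87.9) for liver and blood, 0.05 (27.9) for limb and face, 0.04 (30.1) for somite and muscle, 0.02 (27.5) for the neural tube and 0.01 (28.9) for the heart. Within them Myod1, the muscle determination gene, lay at -4.02 (44 against 423) and Tbx18 at -5.36. The housekeeping call ended with genes of lower signal left out (18.3) and in odd columns (4.07). Highest were Pold2 at 7.72, Acadm at 7.33 and Eif2s1 at 7.25, which had the reads of its neighbour Atp6v1d. Lowest were Sav1 at -8.88 (2 reads against 1572), Olfr1362 at -8.57, Ivd at -8.51 and the antigen-presenting gene Cd1d1 at -8.08. Without the pseudocount, the ratio of Sav1 was -10.50 (-13.54 to -8.64). The larger sums are lower bounds for 7 of the 10 highest genes and 9 of the 10 lowest, among them Pold2, Eif2s1 and the 4 lowest named, and for Tbx18.

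Between the active marks H3K27ac and H3K4me3, no gene list of the embryo lay outside the central range. Housekeeping genes had a median log2 ratio of 0.08 (15.8) and Hox genes of 0.19 (38.8), against 0.20 over all genes. With the deposited values the Hox genes lay at 95.7, within the central range. Neural genes lay lowest, at -0.04 (5.24), with the Notch ligand gene Dll1 at -1.59. Among limb and facial genes (0.22, percentile 45.6), Tfap2a and Lmx1b lay at 4.27 (1118 reads against 41) and 4.25 toward H3K27ac, and among the transcription factors of Polycomb domains (0.19, percentile 30.3), Lhx1 and Evx2 lay at -4.71 and -4.35 toward H3K4me3.

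Heart genes lay at 0.22 (43.2), somite genes at 0.21 (39.8), with Mesp2 at 3.93, and liver and blood genes at 0.18 (42.8). None of the 8 lists, where chance gives 0.4, and 0 of the 24 others fell outside, and with genes of lower signal left out the liver and blood list alone did (2.11). The muscle gene Rapsn was highest at 8.47 (1553 reads against 1), followed by Lce1i at 8.31 and Gjb1 at 7.23. Olfr1362, Ivd and Anks4b were lowest at -9.13 (1 read against 1685), -8.81 and -8.48. Ratios without the pseudocount were 10.17 (7.69 to 15.48) for Rapsn and -11.15 (-16.45 to -8.67) for Olfr1362. Lower bounds are the larger sums of 6 of the 10 highest genes and 10 of the 10 lowest, and of Tfap2a.

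In the comparison of H3K4me3 between adult brain and embryo, which contrasts a mature and a developing tissue, genes of mature neurons and glia lay near the other genes. Neuron genes had a median log2 ratio of 0.79 (0.59 to 1.02) against 0.66 over all genes, with 15 of 24 above that median, and astrocyte genes of 1.00 (0.68 to 1.25), with 10 of 13 above. The synaptic vesicle gene Syp lay at 3.19 (387 reads against 4), the neuronal splicing factor gene Rbfox3 at 1.12 (748 against 51) and the NMDA receptor gene Grin2a at 1.40. Glial genes included S100b at 1.39 for astrocytes, Tmem119 at 1.74 for microglia, and Cnp and Olig2 at 1.88 and 1.32 for oligodendrocytes. Lower in the brain than in the embryo were Ppp1r1b, a marker of striatal neurons, at -2.98 and the developmental genes Tbx18 at -4.70 (255 against 1077), Alx1 at -3.58, Evx2 at -3.34 and Hoxd3 at -2.69.

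None of the 15 brain and embryo lists fell outside the central range, where chance gives 0.75. Among the brain lists, astrocyte genes were at percentile 93.9, neuron genes at 78.1, oligodendrocyte genes at 71.3, microglia and vascular genes at 70.4, thalamus and midbrain genes at 44.2, excitatory neuron genes at 21.8 and inhibitory and striatal neuron genes at 3.59. Embryo lists were at 76.1 (somite), 74.4 (heart), 71.0 (liver and blood), 63.0 (Hox), 44.6 (limb and face), 33.1 (Polycomb domains), 14.1 (housekeeping) and 8.28 (neural tube). Of the 17 paw lists 1 was outside, the inflammatory cytokines at 0.755. Single ratios were highest for Olfr601 at 3.58 (279 reads against 1, and 5.41 with an interval of 2.92 to 10.72 without the pseudocount), Gm19345 at 3.54 and the neural adhesion gene Ntm at 3.54, and lowest for Ivd at -7.80 (41 against 2011), Anks4b at -7.59 and Cd1d1 at -7.54. The embryo sums of 14 of the 15 lowest genes and of Tbx18 are lower bounds. Inhibitory and striatal genes fell outside with spots of more genes (2.32), even columns (1.30) and the share of spots (0.665), and astrocyte genes with the mean of spot shares (98.7), each as the sole list.

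Within each section, the ranks of a list's genes by reads were compared with random lists of equal size. These were drawn from all genes of the section without matching by signal. Their percentiles therefore describe the level of signal and cannot be read like those of the ratios between sections. Hox genes ranked high under all marks, with median ranks of 79.7%, 77.7% and 79.8% for H3K27me3, H3K27ac and H3K4me3 in the embryo, 71.9% in the brain and 74.5% and 85.2% in the arthritis and control paws. Transcription factors of Polycomb domains had median ranks of 71.3% to 80.7%, and both lists lay above percentile 99.5 in all 6 sections. Housekeeping genes had median ranks of 52.3% under H3K4me3, 41.2% under H3K27ac and 39.5% under H3K27me3 in the embryo and 43.6% in the brain, all within the central range. In the arthritis paw, macrophage genes (21.3%, percentile 0.34) and inflammatory cytokines (23.9%, percentile 0.505) ranked low, and in the control paw epidermal genes did (percentile 0.60). These are not contrasts of the paws, since the arthritis file holds 16 of 25, 19 of 31 and 10 of 20 of the members in the control file, macrophage genes were at 33.9% in the control paw, and the cytokines were as low in the brain (percentile 0.535). Of the 65 lists read in their own tissue, 20 fell outside, against 14 with the deposited values and 8 when the random lists were drawn from genes at or above the median.

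Sections that shared a mark or tissue were not the most alike across the genes that both sections of a pair hold. These numbered 9546 to 19046 by pair, and the pairs were not compared over 1 common set of genes. Spearman's rho lay between 0.611 and 0.762 over the 15 pairs (median 0.712), and the paws correlated at 0.659. Embryo pairs with different marks lay between 0.693 and 0.723, pairs of other tissues with the same mark between 0.627 and 0.738, and pairs differing in both between 0.611 and 0.762. After correction for the reliability between odd and even columns, the range was 0.650 to 0.787. The same 7 genes, Gm14569, Cox6b1, Cbr3, Slco2b1, Dnajc21, Tpm4 and Adap1, were among the 50 with the most reads in all 6 sections, out of 9471 genes held by all. Genes are not independent replicates, so the correlations carry no p-value, and with genes at or above the median in both sections the median rho was 0.463.

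**Figure D2:**
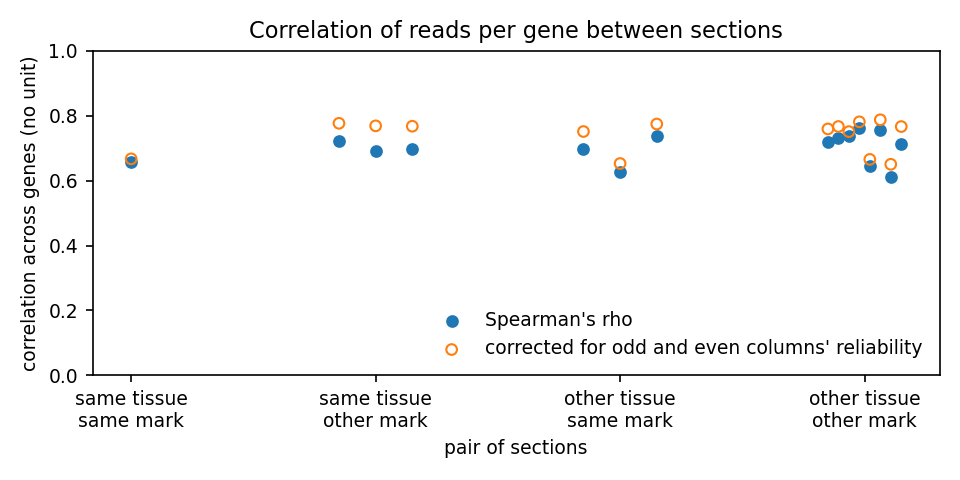
Correlation of reads per gene for the 15 pairs of sections (y axis, no unit), grouped on the x axis by whether the pair shares tissue and mark. Filled points are Spearman's rho and open points the values corrected for reliability, and the points run from 0.611 to 0.787.

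Within sections, few genes were arranged in space beyond what depth alone gives, by a measure that moves with the setting. The share of genes with a Moran's I above the 99th percentile of shuffled spots was 4.61% (4.09 to 5.19) in the arthritis paw and 3.71% (3.36 to 4.11) in the control paw, where spots drawn from a single profile gave 2.01% and 2.37%, and 4% of 200 simulated control paw genes without planted structure lay above. It was 2.23% (1.96 to 2.55) against 1.46% for embryo H3K4me3, 1.54% (1.32 to 1.81) against 1.35% for H3K27me3, 1.37% (1.16 to 1.62) against 1.09% for H3K27ac, and 1.36% (1.10 to 1.70) against 1.22% in the brain. Of the 257 genes above it in the arthritis paw and the 361 in the control paw, 45 and 80 had sums that are lower bounds. So had the 7 with the highest Moran's I: Gm14569 (0.348), Cox6b1 (0.308) and Cbr3 (0.255) in the arthritis paw, Larp4 (0.288), Dram2 (0.279) and Lzts2 (0.264) in the embryo H3K27me3 section and Fam126a (0.258) for H3K4me3. Their scaled reads fell with depth (rho -0.906 to -0.608), except for Lzts2 (0.231). Among genes without that limit, 4833420G17Rik was highest at 0.236 in the embryo H3K4me3 section, with 7 reads, and in the arthritis paw Commd2 at 0.134, with 4311 reads. Summed over their lists, heart genes in the embryo H3K4me3 section (percentile 97.9 of 1000 random lists) and osteoblast genes in the control paw (98.2) were more structured than random lists, and cartilage (1.20) and interferon genes (0.60) in the control paw less. These are 4 of 65 lists, where chance gives 3.25, and the osteoblast genes Alpl and Pdpn held 3.44 and 3.79 times their share in columns 1, 5, 9, 13, 17 and 21. The single profile was not read at other settings, so the shares that follow have no value for depth beside them. The deposited values gave 7.45% to 78.8%. With 4 neighbours the control paw gave 10.7% and the brain 0.262%, the arthritis paw gave 22.9% by presence and 2.90% with spots of more genes, and the control paw 2.99% without columns 1, 5, 9, 13, 17 and 21.

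Clustering into 6 regions placed neighbouring spots together about as often as depth alone does, or less often. Neighbouring spots shared a region in 79.9% of pairs in the brain, 78.6% and 58.7% in the arthritis and control paws, and 86.0%, 80.3% and 89.1% in the embryo sections for H3K27ac, H3K27me3 and H3K4me3. Spots of a single profile with the real depths gave 79.6%, 79.2%, 77.2%, 86.6%, 87.2% and 88.9% in the same order. Spots had been averaged over neighbours before clustering, after which shuffled spots shared a region in 55.4% to 86.0% of pairs. Without that smoothing, the sections gave 30.5%, 38.3%, 42.0%, 38.5%, 40% and 50.9%, and the single profile 30.7%, 56.1%, 51.1%, 64.8%, 55.2% and 73.4%. The largest excess of a section over the single profile was in the arthritis paw with 4 regions, 80.7% against 77.7%. Region 2 of the embryo H3K27me3 section, of 57 spots, was led by Tmem8b with a log2 ratio of 2.53 over the other spots, Lrrc41 at 2.00 and Uqcrh at 1.99. Region 1 of the control paw, of 237 spots, was led by Dmbt1 at 1.25 and Hmgn1 at 1.20, and region 4, of 15 spots, by Tmem8b at 2.58 and Rps4x at 2.39. In the brain the largest region, of 444 spots, was led by Nat9 at 0.61 and Mthfd1l at 0.60. Its spots had a median of 2035.5 reads, against medians of 584 to 990.5 in the other brain regions. Leading genes were taken from the same reads that made the regions, and no such ratios were computed from the single profile.

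Several of these genes lay in straight lines of the array. In all 3 embryo sections genes were raised in the single row 48, with Ifi47 at 13.9, 7.18 and 10.4 times its share for H3K27ac, H3K27me3 and H3K4me3, joined by Flcn and Tmem8b in the first 2 and by Lrrc41 and Uqcrh in the last 2. In both paws Tmem8b, Flcn and Septin3 were raised in row 56, by 10.1, 5.64 and 7.99 times in arthritis, and Ccdc189 in row 21, by 15.4 times in arthritis and 14.9 times in the control. Gene and row pairs numbered 45 in the arthritis paw, 82 in the control paw, 5 in the brain, and 3, 9 and 3 in the embryo for H3K27ac, H3K27me3 and H3K4me3, against 5, 39, 2, 0, 0 and 0 with shuffled spots. In the control paw 85 pairs were with columns, against 5 when shuffled. There, 100 genes chosen in columns 1, 9 and 17, led by Wdr90, Emc3 and Lct, held 5.02% (4.93 to 5.11) of the reads in columns 5, 13 and 21 and 0.747% (0.740 to 0.755) in the other columns, 6.71 times as much (6.57 to 6.85).

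**Figure D3:**
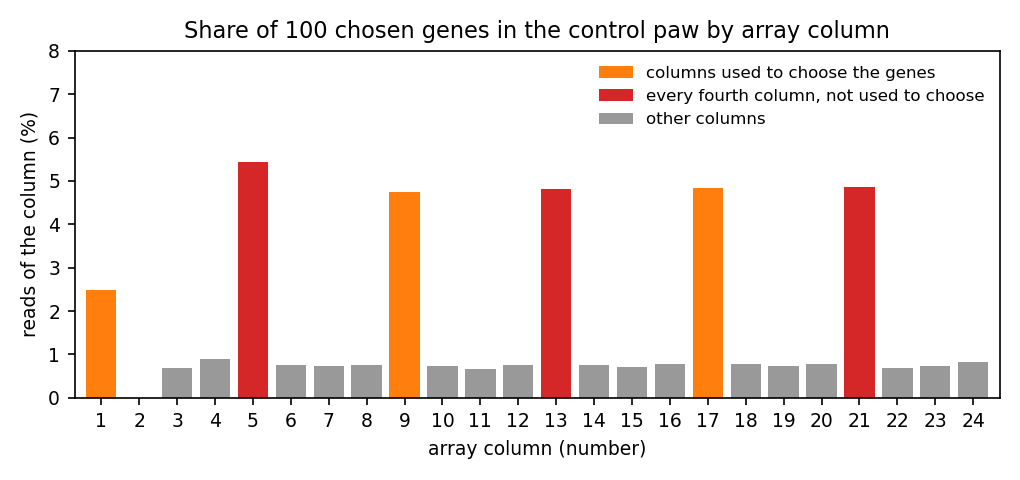
Share of reads held by 100 genes in each array column of the control paw (y axis, percent; x axis, column number). The genes were chosen in the orange columns, and the red columns 5, 13 and 21, which were not used to choose them, hold 5.02% together against 0.747% in the grey columns.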

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

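All tests of explanations in this part were chosen after the result they bear on had been seen. The values in the next paragraph are signal in genes that a comparison left out because 1 of its sections does not hold them.

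The control paw held 1476598 reads, 24.7% of its total (Wilson interval 24.7% to 24.7% after rounding), in 8248 genes that the arthritis paw does not list, led by Larp4 with 18882 reads, Dram2 with 17923 and Dnase1l1 with 15517. The embryo H3K4me3 section held 95090 reads in 6939 genes that the brain does not list, led by Larp4 (3181), Dram2 (3134) and Zc3h13 (2286), and the brain 10615 reads in genes that this embryo section does not list. Among the embryo sections, H3K27me3 held 9051 reads and H3K27ac 7452 in genes that H3K4me3 does not list. H3K27me3 held 3042 reads in genes missing for H3K27ac, and H3K27ac 2471 in genes missing for H3K27me3. H3K4me3 held 1232 reads in genes missing for H3K27ac and 594 in genes missing for H3K27me3.

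The first pattern weighed is that Ifi47, Flcn, Tmem8b, Ccdc189 and other genes were raised in a single row of the array. Tissue structure wider than a row is argued against by the rows on either side in the embryo and paw sections. They held the same genes at 1.02 times (0.968 to 1.07) their share outside the raised row. By section this was 0.676, 0.672 and 0.783 in the embryo for H3K27ac, H3K27me3 and H3K4me3, 1.03 in the arthritis paw and 1.07 in the control paw. The control paw's 82 pairs, against 39 with shuffled spots, say less, since pairs made by single spots give about 1 there in any tissue. In the brain the adjacent rows held its 5 cases at 3.08 times (2.27 to 4.10), and tissue structure stays open there. A cause tied to the position on the array, such as the barcode of that row, remains a candidate explanation: in 16 of 16 cases of a gene raised in both sections of 1 tissue, the row was the same. In 25 cases of a gene raised in sections of different tissues the row was the same in 0, so the genes recur while the row differs. Neighbours that share reads, such as Lrrc41 and Uqcrh, count separately in these numbers, as does a gene in each pair of the 3 embryo sections (Ifi47 3 times, all embryo cases in row 48), and no row was left out of the embryo comparisons.

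The second pattern is the raised share of 100 genes, led by Wdr90, Emc3, Lct and Hmgn1, in columns 1, 5, 9, 13, 17 and 21 of the control paw. Tissue structure is argued against by the columns next to these, which held 1.05 times (1.03 to 1.08) the share of the columns between, and reads of another section of the series by the highest share found there, 0.499% in the embryo H3K4me3 section against 4.63% for the same genes in columns 5, 13 and 21. A cause that follows the array's layout stays open, since genes chosen in columns 1, 9 and 17 were raised 6.71 times in columns 5, 13 and 21, and reads from a library outside this series could also produce it. The columns hold 129 spots with 12.9% of the section's reads, and in the other 5 sections the same procedure gave 1.07 to 1.42 times. Without these columns the neutrophil and epidermal lists of the paw comparison stayed outside, at percentiles 0.23 and 97.9, and the interferon list was within, at 97.1.

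The last pattern is that sections with the same mark did not correlate more across genes than sections with different marks, with Hox genes ranking high under H3K27me3, H3K27ac and H3K4me3 alike. Each pair was read over its own shared genes, and whether these different gene sets shape the pattern was not tested. Counting noise is argued against: after correction for reliability, the median correlation of pairs with the same mark minus that of pairs with different marks was -0.0576, and -0.100 to -0.00533 with any 1 section left out, the last without the arthritis paw. Reads that do not depend on the antibody, for example from accessible or easily sequenced chromatin, may contribute, since the Hox genes lay at percentile 37.8 for H3K27me3 against H3K27ac, and at 96.0 with the deposited values, where a Polycomb mark should place them above the central 95%. Both marks on the same genes in different cells of a whole embryo cannot be told apart from this, because housekeeping genes lay below the central range against H3K4me3 (0.035) but within it against H3K27ac (13.4). GC content was not examined, as no genome sequence was used, and biological differences between the tissues and ages stay open as untested.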

How the results depend on the processing

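The use of recovered reads, and the tests of reads not scaled to depth, of the mean of spot shares, of leaving out array columns 1, 5, 9, 13, 17 and 21, genes with lower-bound sums, the 1% most extreme ratios and spots with part of their lowest values at 0 were chosen after the data were seen. All other alternatives were fixed beforehand. No paired analysis was possible because each group holds 1 section. Of 934 values under alternatives, 851 were counted as unchanged, 15 lost a call, 9 gained one, 56 moved and 3 reversed. Unchanged meant the same call for a list percentile, and a value within the main result's interval for shares of genes or neighbouring pairs. Counts of lists were allowed small changes. Among these were 3 paw lists becoming 2 without the array columns named above, and the lists within sections becoming 14 with the deposited values. Of 801 list percentiles 777 kept their call and none turned to the opposite tail. A kept call allows large shifts within the central range. With the deposited values the Hox genes lay at 96.0 for H3K27me3 against H3K27ac, 96.4 for H3K27me3 against H3K4me3 and 95.7 for H3K27ac against H3K4me3. The trimmed mean was run for the paws alone, since in the other comparisons it leaves most genes at 0. The median log2 ratio of all genes ranged over the alternatives from -0.05 to 0.18 for the paws, -0.16 to -0.02 for H3K27me3 against H3K27ac, 0 to 0.35 for H3K27me3 against H3K4me3, 0.03 to 0.36 for H3K27ac against H3K4me3 and 0.06 to 0.80 for brain against embryo, which is why lists are read against matched random lists. Embryo medians of 7 to 14 reads per gene limit the ratios of single genes there. Except where stated, the cause was not tested.

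The 3 paw lists outside the central range became 1 with a pseudocount of 1, 1 with genes at or above the median signal (with 0 lists shared) and 1 with even columns. For H3K27me3 against H3K27ac, 0 lists became 1 with the deposited values. For H3K27me3 against H3K4me3, 1 list became 0 with genes at or above the median signal and 0 with odd columns, and for H3K27ac against H3K4me3, 0 became 1 with genes at or above the median. For brain against embryo, 0 became 1 with spots at or above the 25th percentile of genes with reads, 1 with even columns, 1 with the share of spots and 1 with the mean of spot shares. The 20 lists outside within sections became 8 when random lists were drawn from genes at or above the median, by which the lists are set against genes of higher rank. The median correlation of 0.712 was 0.463 with genes at or above the median in both sections and 0.648 as Pearson's r of log2 values.

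Shares of genes above shuffled positions moved as follows, in the order brain, embryo H3K27ac, embryo H3K27me3, embryo H3K4me3, arthritis paw and control paw. The deposited values gave 24.7%, 8.70%, 7.45%, 14.7%, 22.0% and 78.8%. Reads not scaled to depth gave 5.91%, 3.95%, 8.78%, 9.22%, 59.4% and 22.2%, in which depth itself is arranged in space. Presence above the gene's median gave 3.66%, 2.09%, 4.01%, 6.49%, 22.9% and 8.16%. With 4 neighbours the brain gave 0.262%, the embryo 1.13%, 1.21% and 1.54%, and the control paw 10.7%. In the brain these 4 are diagonal spots in columns of the other parity, which differ in depth, whereas the 8 neighbours include spots of the same parity. Spots at or above the 25th percentile gave 1.41% for embryo H3K4me3, 2.90% for the arthritis paw and 4.44% for the control paw, which gave 2.99% without columns 1, 5, 9, 13, 17 and 21.

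The excess of neighbouring pairs in 1 region over shuffled spots, in percentage points, was 8.39 in the brain and became 5.41 with 8 regions, 1.61 without smoothing and 21.6 with the deposited values. For embryo H3K27ac it was 0 and became 4.44 without smoothing and -3.41 with the deposited values. For embryo H3K27me3 it was -3.15, became 0 with 8 regions and reversed to 0.112 with 4 regions, 1.12 without smoothing and 4.27 with the deposited values. For embryo H3K4me3 it was 6.58 and became 10.3 with 4 regions, 0.808 with 8, 21.1 without smoothing and 22.5 with the deposited values. The arthritis paw's 3.41 became 5.76, 5.88, 14.1 and 7.04 in the same order, and the control paw's 3.25 became 6.44 with the deposited values.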

Other observations

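The comparisons in this part were chosen after the data were seen, apart from the gene lists, which were fixed beforehand.

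Gene lists of tissues other than the one sectioned ranked high in several sections. Excitatory neuron genes had a median rank of 76.5% in the arthritis paw (percentile 99.3 of random lists) and 83.6% in the control paw (99.96), and 82.9% to 86.5% under H3K27me3 and H3K27ac in the embryo. Limb and facial genes had a median rank of 69.0% in the brain (98.7) and 85.8% in the control paw (100), and 64.7% in the arthritis paw (96.1, within the central range), whose file holds 33 of 36 members. Genes of the NF-kB and AP-1 response, a list written for the paw, ranked at 78.4% in the control paw (99.99) and, over the 20 of 28 members that its file holds, 58.3% in the arthritis paw (78.8, within). It ranked at 77.3% for embryo H3K27ac (99.9) and 78.8% for embryo H3K27me3 (99.99). The ranks are taken over the genes of each file, so they do not compare the paws. In the brain 5 of 25 lists of other tissues lay above the central range and 1 below it, and in the control paw 8 of 15 lay above it.

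Most genes with at least 100 reads varied between spots about as much as their counts allow, and a minority varied more. Only genes with that many reads were measured: 6781 in the brain, 10254 in the arthritis paw and 12406 in the control paw. In the embryo they numbered 844, 1262 and 580 for H3K27ac, H3K27me3 and H3K4me3, a small part of the genes. The median ratio of variance to that of Poisson counts was 1.00 to 1.03 over the sections. From 4.10% of the measured genes in the brain to 13.6% in the control paw exceeded the ratio that 1% of simulated Poisson genes exceed. It lay above 2 in 0.398% of genes with at least 100 reads in the brain and 2.87% in the control paw. Cdc27, a subunit of the anaphase-promoting complex, reached 9.30 in the control paw, Ifi47, an interferon-induced GTPase, 7.13 for embryo H3K4me3, Slc2a10 6.22 in the arthritis paw and Abcd2, a peroxisomal transporter, 4.29 in the brain. Of their reads 51.2%, 50%, 22.4% and 49.5% lay beyond the zone of exact numbers, and row 48 held 168 of the 336 reads of Ifi47. Npas3, Abcd2 and Slc4a7 were among the 10 highest in both paws and in the brain.

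Reads were spread unevenly over the array in the brain section. Its odd columns held 18.6% of the reads, with a median of 589 reads per spot against 2653.5 in even columns, while in the other 5 sections odd columns held 40.4% to 54.4%. Brain spots lie on every other position of the array. Its odd columns are therefore also rows of a single parity, and the difference cannot be assigned to columns rather than rows. The factor by which the common list of values had been multiplied in each spot was arranged in space in all 6 sections, with a Moran's I of its log2 between 0.275 and 0.545, and its largest value was 5.31 to 125586 times its smallest.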
